A study of Mus musculus with 12 samples.

How the data were processed

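Total RNA of 12 sorted lymphoma samples, 6 wildtype and 6 homozygous for the Smchd1 gene trap, was hybridised to Illumina MouseWG-6 v2 arrays, 1 array per sample, by the authors. The deposited scanner tables hold the average bead intensity of each probe, neither background-corrected nor normalized per the file headers. Beside it they hold a detection score, a fraction that equals 1 minus the detection p-value, and a further deposited table gives the same intensities with the detection p-value itself, computed against negative control probes. The deposited control table holds the intensity of the control probes. The authors also deposited processed log2 values, made with neqc in limma 3.12.1 under R 2.15.1 per the labels. The intensities of the 2 scanner tables were equal for 100% of values, and neqc rerun here gave the authors' log2 values to within 5.00e-09. Every value column was matched to its sample through the labels, and 0 columns were left unmatched.

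Starting from the deposited intensities, background was corrected with neqc of limma 3.58.1 in R 4.3.3, using 936 negative control probes, an offset of 16 and quantile normalization. All differences are on the log2 scale, null minus wildtype. Probes with a detection p under 0.05 on at least 3 of the 12 arrays were kept, 18921 of 45281. The 95th percentile of intensity was 8.68 times the median of the negative controls on null 2, the lowest array, and 24.7 times on null 4, the highest. Probe annotation came from the deposited tables. Current symbols, chromosomes and neighbouring genes came from a reference gene table (assembly GRCm38.p6), of which no coordinates are printed because the array files name no assembly. Of the probes on the array 27400 matched a symbol, 8341 a synonym and 9540 nothing, and 16364 of the probes kept had a match.

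Each probe was fitted with lmFit and eBayes of limma without covariates, and p-values were adjusted by Benjamini-Hochberg over the probes kept, with a threshold of 0.05. Intervals are 95% intervals from the moderated fit. For Smchd1 an exact two-sided permutation test over all 924 assignments of the arrays was added. The same test for Mkrn3, C030034I22Rik and Ndn was chosen after their values were seen, and its p is not adjusted for the choice of these genes. Where all arrays of a genotype lay under detection, a fold is given as a lower bound where this exceeds 1, and the mean differences of gene lists include such genes at their normalized values. The bound compares group means, with undetected values raised to the lowest detected value of their array. It makes no allowance for the spread between arrays and is not the end of an interval. Gene lists, 22 in number, cover loci that depend on Smchd1, pathways of Myc lymphoma and markers of B cell stages and of other cell types, and Smchd1 is in none of them. A list was tested with camera at its preset correlation of 0.01 when at least 3 members were kept, with 1 probe per gene, the one of highest mean, and Benjamini-Hochberg adjustment over 21 lists. Camera with an estimated correlation and fry, both of limma, were run beside it. The share of called genes within 10 Mb of Smchd1 was compared with all other genes by Fisher's exact test, two-sided.

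The comparison, its tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, apart from those permutation tests, the share of flank probes at an unadjusted p under 0.05, and 3 alternatives named in the closing section. The rule named Smchd1, then up to 12 genes per direction among those past the threshold, filled up to 12 by the smallest unadjusted p and then given as values only, and up to 4 members per list. The alternatives were no background correction, an offset of 50, cyclic loess, the authors' processed values, no filter, a filter at detection p under 0.01 on at least 6 arrays, slide as a block, each slide alone and replicate number as a block. The remaining ones were a trended and robust variance, array weights, a score of Y-linked genes and a score of B cell stage as covariates, probes of chromosomes X and Y left out, probes of a gene averaged, and each array left out in turn. For each slide alone and wherever arrays were left out, normalization and the detection filter were rerun on the arrays used. The measured members of a list can therefore differ from those over all arrays. For the lists the estimated correlation, fry and the mean of a gene's probes were added.

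The limma fit was tested on 20 simulated sets with the spread of these arrays and 200 changed probes each among 18921. At a log2 change of 1 it recovered 21.3% of changed probes, at 2 it recovered 77.2% and at 3 it recovered 92.0%, and 44 of 2580 calls (1.71%) were false. The changes were added to values already background-corrected, normalized and filtered, so those steps were not tested. Changes of dim probes, which the background narrows, may be recovered less often. The replicate numbers of the labels were not treated as pairs, since the deviations of arrays with the same number from their group means correlated between -0.25 and 0.66, and 4 of the 12 arrays correlated best with the array of their own number. The sex of the animals, the tumour sites and the sorting gates are not given in the labels and were not used here. No array was left out.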

Results

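Gene expression was measured in 12 end-stage lymphomas of mice that carry the Eµ-Myc transgene, which drives the oncogene Myc from an immunoglobulin heavy chain enhancer and gives rise to tumours of the B cell lineage. Of these, 6 were wildtype for Smchd1 and 6 were homozygous for a gene trap in Smchd1, which encodes a chromatin protein that takes part in silencing of the inactive X chromosome, of imprinted genes and of clustered protocadherins. The labels give the strain of all samples as C57BL/6 and say that the cells were purified by sorting, without naming the markers sorted on. Each sample was run on 1 Illumina MouseWG-6 v2 array, and each of the 2 slides held 3 wildtype and 3 null arrays. The share of probes detected over background ranged from 32.9% to 39.1% per array, and 18921 of the 45281 probes on the array were kept for testing. The number of arrays, 6 per genotype, limits the precision of every difference given here. The labels do not say whether the 6 samples of a genotype came from separate mice.

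The comparison of null with wildtype tumours asks which genes differ in expression between end-stage Myc lymphomas that arose with and without functional Smchd1. Smchd1 itself fell by 4.37 on the log2 scale in the null tumours, a 20.7-fold lower level after background correction. The imprinted gene Mkrn3, which was detected on 0 of 6 wildtype arrays and on 6 of 6 null arrays, rose at least 3.41-fold on the same scale. One probe of C030034I22Rik, a gene on the chromosome of Smchd1, fell by 2.91. These were the 3 probes past an adjusted p of 0.05, for 3 gene symbols, with 1 higher and 2 lower in null tumours.

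The Smchd1 probe with the highest mean (4150612, chromosome 17) had a log2 value of 10.15 ± 0.31 (SD, n = 6) in wildtype and 5.78 ± 0.67 (SD, n = 6) in null tumours. The difference was -4.37 with an SE of 0.29, a 95% interval from -5.00 to -3.74 and a limma adjusted p of 2.13e-05. All 6 null values lay below all 6 wildtype values (exact permutation p = 0.00216, two-sided, the smallest that 6 against 6 arrays can give), and the difference was -4.66 on slide 1 and -4.09 on slide 2. The probe stayed above background on 6 of 6 null arrays. A second Smchd1 probe (2360553) was at 5.26 ± 0.37 in wildtype and 4.46 ± 0.14 in null tumours (SD, n = 6 each), where 0 null arrays had it above background. Probe 160735 was at 6.30 ± 1.05 and 5.41 ± 0.57, and neither of these dimmer probes passed the threshold. The files do not place the probes relative to the trap. Sizes depended on the background correction, and without it the difference was -3.14 for Smchd1 and -1.49 for C030034I22Rik, while an offset of 50 gave -3.69 for Smchd1, -2.01 for C030034I22Rik and 1.32 for Mkrn3. With the kept probes of Smchd1 averaged its difference was -2.02.

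Mkrn3, which encodes a zinc finger protein expressed from the paternal allele, had a log2 value of 4.57 ± 0.15 in wildtype and 6.76 ± 0.55 in null tumours (SD, n = 6 each, probe 1990504, chromosome 7). The difference of 2.20 had an SE of 0.24, a 95% interval from 1.68 to 2.72 and a limma adjusted p of 0.00276. It was 1.89 on slide 1 and 2.503 on slide 2, and all 6 null values lay above all 6 wildtype values (exact permutation p = 0.00216). Ndn, which encodes necdin and is also expressed from the paternal allele of the same cluster, was at 4.62 ± 0.26 in wildtype and 7.17 ± 1.41 in null tumours (SD, n = 6 each, probe 4490367). Its difference of 2.55 had an SE of 0.53 and a 95% interval from 1.42 to 3.69. The mean level was at least 4.51-fold higher after background correction, since Ndn was detected on 0 wildtype and 6 null arrays. All 6 null values again lay above all 6 wildtype values (exact permutation p = 0.00216, the smallest possible), yet over all probes the limma adjusted p was 0.954. In raw intensity 5 of the 6 null values of Ndn lay above all wildtype values, and after quantile normalization without background correction all 6 did, with 6.64 ± 0.11 in wildtype and 7.94 ± 0.88 in null tumours (SD, n = 6 each). Without background correction Mkrn3 was at 6.62 ± 0.07 in wildtype and 7.58 ± 0.32 in null tumours (SD, n = 6 each), a difference of 0.96 that no longer passed the threshold (limma adjusted p = 0.0695).

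The 2 probes of C030034I22Rik gave different results. Probe 3190392 was at 7.77 ± 0.60 in wildtype and 4.86 ± 0.30 in null tumours (SD, n = 6 each), a difference of -2.91 (SE 0.27, 95% interval from -3.49 to -2.33) with a limma adjusted p of 5.78e-04. It was detected on 6 wildtype arrays and 1 null array, and the difference was -3.14 on slide 1 and -2.69 on slide 2 (exact permutation p = 0.00216 over both slides). Probe 1660338 was at 5.81 ± 0.99 in wildtype and 6.18 ± 0.84 in null tumours, a difference of 0.37 that did not pass the threshold. With the probes of a gene averaged the difference was -1.27 and the call was lost.

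**Figure D1:**
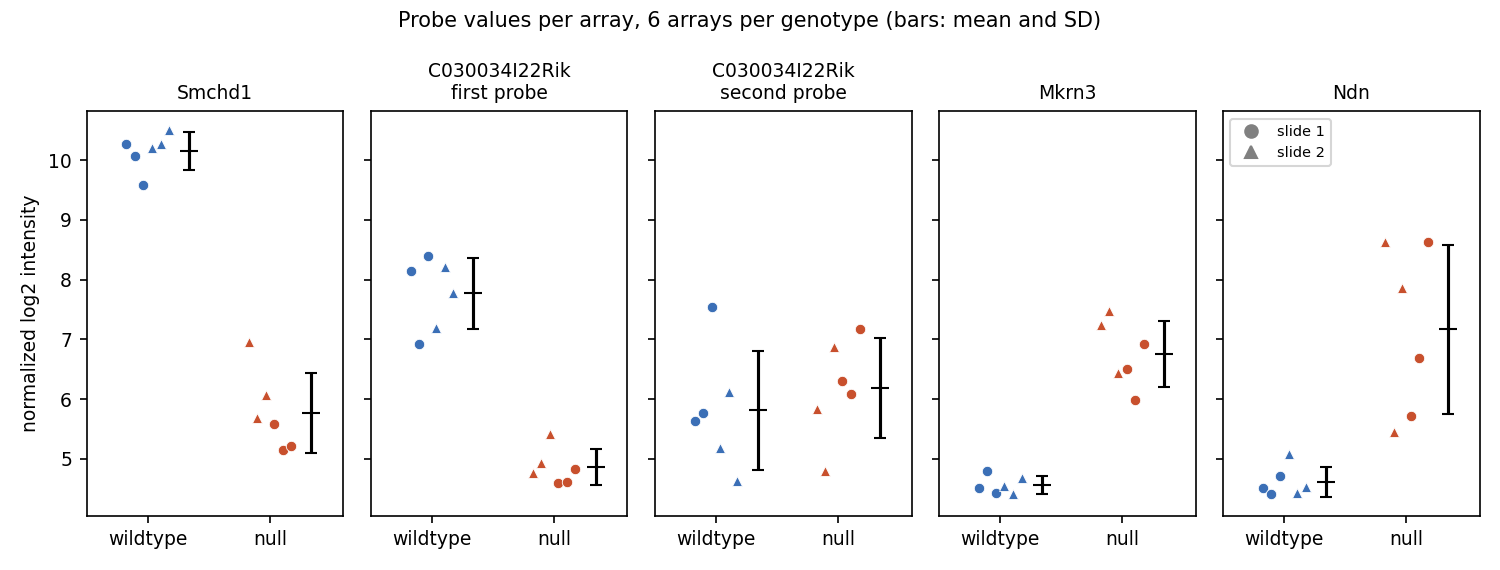
Normalized log2 intensity (y axis) of Smchd1, both C030034I22Rik probes, Mkrn3 and Ndn on each of the 12 arrays, by genotype (x axis), with circles for slide 1, triangles for slide 2 and bars for the mean and SD of 6 arrays. Smchd1 and the first C030034I22Rik probe were lower on all 6 null arrays than on any wildtype array, Mkrn3 and Ndn were higher on all 6, and the second C030034I22Rik probe overlapped between genotypes.

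None of the other probes passed the threshold, and the genes next in order are given as values. Among those with higher means in null tumours were 1700030C10Rik, a long noncoding RNA (1.98, SE 0.31, limma adjusted p = 0.121), and Pkp4, which encodes a junction protein of the plakophilin family (3.37, SE 0.59, limma adjusted p = 0.269). 1700030C10Rik passed the threshold without wildtype 2 (2.24, adjusted p = 0.00148) and Pkp4 without null 5 (3.75, adjusted p = 0.0490). These Pkp4 values are of probe 6940592. Another kept Pkp4 probe, 3310437, had a difference of 1.32, and probes 4250438 and 4540270, which were not kept, had 0.20 and 0.07. The log2 differences of the other genes with higher means were 1.23 for LOC382707, 1.49 for LOC382691, 1.46 for the neuronal RNA-binding protein gene Elavl2, 0.85 for the transcription factor gene Sox12, 0.86 for the amino acid transporter gene Slc16a10, 1.35 for Bbs7 and 1.80 for the cell adhesion gene Ncam1, while Macrod2, detected on 0 wildtype arrays, was at least 1.88-fold higher. Among genes with lower means were Olfr378 (-0.67), the tryptophan tRNA ligase gene Wars (-0.76), Carmil2 (-1.06), Kansl3 (-0.71), Tmem143 (detected on 0 null arrays, at least 1.14-fold lower), the cyclin G2 gene Ccng2 (-0.70) and Arhgef6 (-0.62). The last of them were Pear1 (-1.01), Pml (-0.69), which encodes the scaffold protein of PML nuclear bodies, and Haghl (-0.58). In limma 271 probes had an unadjusted p under 0.05, with 142 higher and 129 lower, where 946 would be found by chance. The groups did not overlap for 15 probes, or 0.0793% of those kept, where chance gives 0.216%.

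Of the 22 gene lists fixed before the data were examined, 21 had at least 3 measured members and were tested as groups. The list of the Snrpn imprinted cluster passed the threshold with a mean difference of 1.25 over 4 members, which Mkrn3 and Ndn carried. At the correlation between genes that camera presets, markers of NK and cytotoxic cells (mean -0.61, 11 members) and of erythroid cells and megakaryocytes (mean 0.61, 11 members) passed as lists, with 0 members of either past the threshold on their own. With an estimated correlation the Snrpn cluster alone passed.

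Of the 10 genes named in the Snrpn cluster list 4 were kept, and all had higher means in null tumours, with a camera adjusted p of 2.57e-08, an adjusted p of 0.00615 with an estimated correlation and 0.0227 with fry. Adjusted over the list alone 2 genes rose, Mkrn3 and Ndn, and over all genes tested 1, Mkrn3. In the other 20 lists 0 genes passed when adjusted over the list alone. Ube3a, a ubiquitin ligase gene, had a difference of 0.25 and the lipid transporter gene Atp10a of 0.01. Mkrn3 and Ndn passed the detection filter through the null arrays alone, while Magel2, Peg12 and the 3 probes of Snurf were on the array and not kept, since each was detected on at most 1 array per genotype. With no filter on detection the mean shift of the list was 0.72 (adjusted p = 6.62e-04), and without background correction it was 0.58. The shift was 1.604 on slide 1 alone and 1.41 on slide 2 alone. Each slide was normalized and filtered anew, so these values need not rest on the same 4 members. With slide as a block its adjusted p was 3.30e-07. Other loci of the kind that Smchd1 is known to silence did not pass. The 5 clustered protocadherins, cell adhesion genes, had a mean difference of 0.14 (camera adjusted p = 0.216), with -0.54 for Pcdhgc5. Pcdha7 and Pcdhb4 were each detected on 0 wildtype and 3 null arrays, with Pcdha7 at least 1.32-fold higher. The 22 other imprinted genes had a mean of 0.07 (adjusted p = 0.368), with Peg3, detected on 0 wildtype arrays, at least 1.35-fold higher and -0.89 for the growth factor gene Igf2. The 12 Hox genes had a mean of -0.12 (adjusted p = 0.368), with Hoxa4, detected on 0 wildtype arrays, at least 1.22-fold higher and -0.41 for Hoxc10. Of the Igf2r cluster 1 member was measured, so it was not tested.

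Markers of NK and cytotoxic cells had lower means in null tumours for 11 of 11 members (camera adjusted p = 2.83e-06), among them the chemokine genes Ccl5 (-1.49) and Xcl1 (-0.64). The NK receptor genes Klre1 and Klrb1c were detected on 0 null arrays and were at least 1.44-fold and 1.05-fold lower. The list did not pass with an estimated correlation (adjusted p = 0.409) or with fry (adjusted p = 0.896). Its mean shift was -1.36 on slide 1 alone and 0.04 on slide 2 alone, each slide normalized and filtered anew. In the normalization over all arrays the means of the 11 members on slide 2 were 5.33, 5.63 and 7.07 on wildtype 4, 5 and 6. They were 5.62, 6.18 and 5.49 on null 1, 2 and 3, so the null arrays averaged lower there too. Without wildtype 1 the shift of the NK list was -0.32 (adjusted p = 0.05004, not past the threshold). Markers of erythroid cells and megakaryocytes had higher means for 10 of 11 members (camera adjusted p = 0.00341), with 1.44 for the anion exchanger gene Slc4a1, 1.38 for ERAF, the array's name for the gene of an alpha globin stabilizing protein, and 1.23 for the carbonic anhydrase gene Car1. This list did not pass with an estimated correlation (adjusted p = 0.409) or with fry (adjusted p = 0.896). Its mean shift was 0.18 on slide 1 alone and 1.02 on slide 2 alone, each again normalized and filtered anew. The erythroid list did not pass without wildtype 2 (0.47, adjusted p = 0.0634), null 1 (0.49, adjusted p = 0.0691) or null 2 (0.40, adjusted p = 0.143), while without wildtype 5 the shift was 1.01. With array weights it was 0.21 and did not pass (adjusted p = 0.439). Without background correction the mean shift was -0.32 for the NK list and 0.38 for the erythroid list, which with no filter on detection was at 0.33. In simulated data with no change, camera with its preset correlation called 5.55 of the 21 lists on average, and 0.05 with an estimated correlation.

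None of the lists on Myc lymphoma and the cell cycle passed the threshold. The 27 p53 target genes had a mean difference of 0.15 (camera adjusted p = 0.0814), with 1.36 for Zmat3 and -0.88 for Trp53inp1. The p53 list passed without wildtype 6 (0.18, adjusted p = 0.0275), null 3 (0.16, adjusted p = 0.0355), null 4 (0.15, adjusted p = 0.0349) or null 5 (0.21, adjusted p = 0.00909), and on slide 2 alone (0.25, adjusted p = 0.00352) or with the sex marker score (0.17, adjusted p = 0.0459). The 23 tumour suppressors and survival genes of Myc lymphoma had a mean of 0.09 (adjusted p = 0.418), with -0.91 for Bmf, which encodes a protein that promotes cell death, and 0.58 for Bad. The means were 0.02 for 36 Myc target genes (adjusted p = 0.368), 0.10 for 25 G1/S genes (adjusted p = 0.368), which include the DNA replication genes Fen1 (0.39) and Rpa2 (0.42), and 0.09 for 27 G2/M genes (adjusted p = 0.368). Ect2, a gene of cell division in the last of these lists, had a difference of 0.37. Without null 1 the Myc target list (0.11, adjusted p = 0.0115), the G1/S list (0.30, adjusted p = 0.00349) and the G2/M list (0.35, adjusted p = 0.00174) passed. Without wildtype 4 the G1/S list (0.23, adjusted p = 0.0282) and the G2/M list (0.23, adjusted p = 0.0282) passed, and without wildtype 3 the G2/M list (0.23, adjusted p = 0.0368). Without wildtype 1 both passed in the other direction, G1/S at -0.25 (adjusted p = 1.50e-04) and G2/M at -0.28 (adjusted p = 4.10e-04). For these 3 lists the slides gave opposite directions, each past the threshold. The lowest wildtype array for all of them, wildtype 1, was on slide 1, and the lowest null array, null 1, on slide 2. On slide 1 alone the means were 0.27 for Myc target genes (adjusted p = 0.00124), 0.70 for G1/S genes (adjusted p = 4.91e-06) and 0.87 for G2/M genes (adjusted p = 2.32e-06), and on slide 2 alone -0.23 (adjusted p = 0.0111), -0.50 (adjusted p = 1.85e-05) and -0.75 (adjusted p = 7.52e-08). All these calls use the preset correlation. The correlation estimated over the 12 arrays was 0.80 for G1/S genes, 0.82 for G2/M genes and 0.39 for Myc target genes, with an adjusted p of 0.828 for each, and for p53 target genes the adjusted p was 0.409. The means of 28 chromatin silencing factors (0.02, adjusted p = 0.655), 31 interferon response genes (median -0.05, adjusted p = 0.753) and 24 immediate early and stress genes (0.03, adjusted p = 0.418) did not pass either. In these lists Bmi1 had a difference of 0.52, Mx2 of 0.73, Tap1 of -0.47 and Klf4 of 0.79.

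The markers of B cell stages and of the remaining cell types did not pass the threshold. The mean difference was -0.36 for 15 pro-B and pre-B cell markers (camera adjusted p = 0.216), -0.11 for 27 mature B cell markers (adjusted p = 0.418) and -0.28 for 16 germinal centre and plasma cell markers (adjusted p = 0.137). Among these genes were Sox4 (-0.98), Klf2 (-0.62) and S1pr2 (-0.99). The mean was -0.15 for 19 T cell markers (adjusted p = 0.368), with Zap70, a kinase of the T cell receptor pathway, at -1.32. It was 0.22 for 27 monocyte, macrophage and granulocyte markers (adjusted p = 0.216), with the mannose receptor gene Mrc1 at -0.40, and -0.13 for 8 stromal and endothelial markers (adjusted p = 0.706), with Apoe at -0.60 and the chemokine gene Cxcl12 detected on 0 wildtype and 3 null arrays. The 4 Y-linked genes had a mean of -0.51 (adjusted p = 0.0729), with Eif2s3y at -0.999 and Ddx3y at -0.83, and both were lowest on the array null 6. Several of these lists passed with 1 array left out, and T cell markers passed with array weights (-0.42, adjusted p = 0.0484). Pro-B and pre-B cell markers passed without wildtype 2 (-0.70, adjusted p = 0.00872) or null 4 (-0.56, adjusted p = 0.0348), and germinal centre and plasma cell markers without wildtype 3 (-0.46, adjusted p = 0.00394) or null 5 (-0.37, adjusted p = 0.0219). Mature B cell markers passed without null 1 (-0.47, adjusted p = 0.00349), T cell markers without null 1 (-0.70, adjusted p = 1.28e-04) or wildtype 3 (-0.35, adjusted p = 0.0366), and monocyte markers without null 4 (0.42, adjusted p = 0.0111). The Y-linked list passed without wildtype 3 (-0.51, adjusted p = 0.0366), wildtype 6 (-0.55, adjusted p = 0.0398), null 1 (-0.65, adjusted p = 0.0191), null 3 (-0.58, adjusted p = 0.0355), null 4 (-0.57, adjusted p = 0.0417) or null 5 (-0.57, adjusted p = 0.0309), and without null 6 it was at -0.18 (adjusted p = 0.427). These calls use the preset correlation too, and the estimated one was not run with arrays left out. Over the 12 arrays it gave an adjusted p of 0.828 for mature B cell, T cell and monocyte markers (correlations of 0.48, 0.53 and 0.31), 0.821 for pro-B and pre-B cell markers, 0.661 for germinal centre and plasma cell markers and 0.409 for Y-linked genes.

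**Figure D2:**
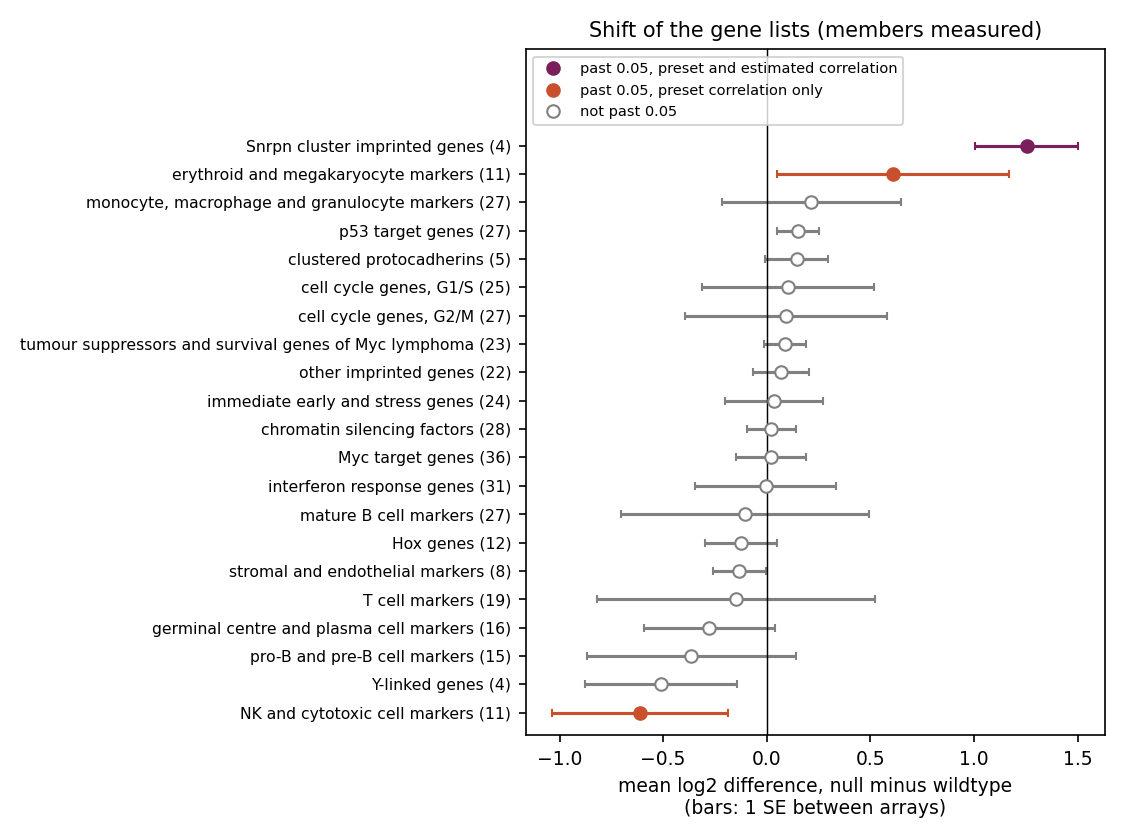
Mean log2 difference, null minus wildtype (x axis), of each of the 21 gene lists (y axis, with the number of members measured), where bars show 1 SE between arrays. The Snrpn cluster lies at 1.25 and passed with the preset and the estimated correlation, while the NK list at -0.61 and the erythroid list at 0.61 passed with the preset alone.

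The genes within 10 Mb of Smchd1 were compared with all others because a targeted allele can carry flanking sequence of the stem cells it was made in. Of 66 measured genes in this part of chromosome 17, 1 was called, C030034I22Rik, against 1 of 10383 genes elsewhere, Mkrn3 (Fisher's exact test, two-sided, p = 0.0126). In the reference annotation 30 genes lie between Smchd1 and C030034I22Rik, 8 of them protein-coding. Of the 101 other probes kept in the flank 5 (4.95%) had an unadjusted p under 0.05, against 263 of 18815 probes elsewhere (1.40%, Fisher's exact test, two-sided, p = 0.0145), where probes of a gene are not independent. The distribution over chromosomes was not tested, because 3 gene symbols passed the threshold and the test had been set to need 20.

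The tumours differed from one another more than the genotypes did. Genotype took up 5.25% of the variance over the probes kept, where an arbitrary split of the arrays takes 9.09% and the slides took 11.5%. The first principal component, with 28.3% of the variance, set wildtype 1 and null 1 apart, and the second, with 25.7%, wildtype 2 and null 2. Between the slides 491 probes passed the threshold in a fit with genotype as a further term, 85 higher and 406 lower on slide 2. With slide as a block 3 probes differed between genotypes, those of Smchd1, Mkrn3 and C030034I22Rik.

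**Figure D3:**
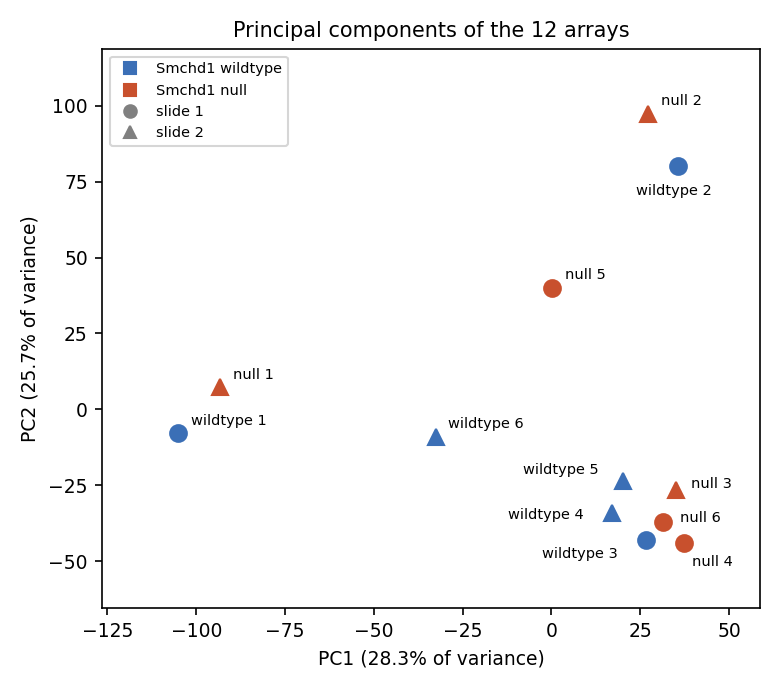
First principal component (x axis, 28.3% of the variance) and second (y axis, 25.7%) of the 12 arrays, with colours for genotype and shapes for slide. Wildtype 1 and null 1 lie apart on the first component and wildtype 2 and null 2 on the second, so that arrays of both genotypes share each position.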

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

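The tests of the second C030034I22Rik probe and of a variant under the first, the share of flank probes at an unadjusted p under 0.05, the tests of slide, background correction and B cell stage for Mkrn3 and Ndn, and the tests of null 6 were chosen only after the result was seen. The predictions for the divisions of the arrays and for the whole flank were written before those tests were run. Both are still framed by the main results. The flank test leaves out C030034I22Rik, and the divisions are compared by the called probes, the called lists and the Snrpn cluster.

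The values below stood far from the other 5 arrays of their genotype by Dixon's ratio of the gap to the range. This was found for 26 of 188 groups of values (18 of 146 for genes and 8 of 42 for gene lists), where chance gives about 1 in 20, or 9.4. Null 6 and wildtype 1 had 5 each, wildtype 2, 3, 4 and 5 and null 1 had 3 each, and null 2 had 1.

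On wildtype 1 the log2 means of the lists were lowest among wildtype arrays for G1/S genes (7.87), G2/M genes (7.52) and Myc target genes (10.30), as was the gene Rpa2 (7.38), while its Y-linked list was highest (8.20). On null 1 the G1/S list was lowest among null arrays (8.77), and the T cell marker list (9.08) and Pcdha7 (7.58) were highest. Wildtype 2 had the highest wildtype value of 1700030C10Rik (6.20) and Ncam1 (6.63) and the lowest of Ccnd2 (4.85). Wildtype 3 was highest for Igf2 (8.46), Elavl2 (5.81) and Kansl3 (6.32). Wildtype 4 was highest for Atp10a (7.10), Bmi1 (7.83) and the Snrpn cluster list (6.07). Wildtype 5 was highest for Car1 (8.72), ERAF (8.52) and Peg3 (5.10). Among null arrays null 2 was highest for Hoxa4 (6.72). Null 6 was highest for Igf2 (5.11) and lowest for Ube3a (6.17), Eif2s3y (4.48), Ddx3y (7.26) and the Y-linked list (5.36).

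The arrays were also divided into 6 and 6 in 100 of the 462 possible ways, the real division included. As many as the real 3 probes passed the threshold in 3 divisions, so chance alone is excluded at 1 in 20 for this count. The real 3 include the probe of Smchd1, the gene that defines the groups, so the count does not test for a wider effect. Another division gave 2 probes, and the highest other count was 657. That highest count came from the division that follows the 2 slides, fitted without genotype as a term (491 probes with it), which shows a structure of the samples by slide, and with slide as a block the genotypes still differed in 3 probes. The mean shift of the Snrpn cluster was as large in 1 division, the real one, with 1.25 against 1.20 for the next highest. A called gene near Smchd1 appeared in 2 divisions, with up to 2 such genes. That number cannot test nearness to Smchd1, since the other divisions had a median of 0 called probes anywhere. For the mean shift of the Snrpn cluster the count is under 1 in 20 for that list taken alone. It makes no allowance for the 21 lists tested, so it does not exclude chance. For the 3 gene lists past the threshold at the preset correlation chance is not excluded either, since 79 of the 100 divisions gave 3 or more lists and the highest gave 13.

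In null tumours 1 probe of C030034I22Rik was lower on all 6 arrays. A lower level of the whole transcript is argued against by the second probe, whose null values lay 1.05 above its wildtype values with their signal over background lowered by 2.33, the smallest fall in the interval of the first probe (exact permutation p = 0.0303 with background at the 95th percentile of undetected probes, 0.0108 with it at their median). A change of the whole flank of Smchd1 is argued against by the other 101 probes there, whose median size of the moderated t lay at percentile 9.47 of random probe sets of that number, while a change of a few genes in it stays open, since 4.95% of these probes had an unadjusted p under 0.05 against 1.40% elsewhere. A sequence variant under the first probe, carried along with the targeted allele, remains a candidate explanation, since the second probe was detected on 5 of 6 null arrays while the first was detected on 1. Probes that read different transcripts of the gene could give the same picture, which was not tested.

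Mkrn3 and Ndn were higher on all 6 null arrays. A difference between slides is balanced by the design, since each slide held 3 wildtype and 3 null arrays. The gap between the lowest null and the highest wildtype array within a slide was at least 0.37 for both genes on both slides. Given the separation over all 12 arrays this gap had to be positive, so it is no further test. The B cell stage score ranged alike in both genotypes, from 1.38 to 5.43 in wildtype and from 1.68 to 5.21 in null tumours. That balance argues against stage, as this score measures it, as the whole cause. A fit with so balanced a score could hardly move the differences and adds little. With the score the limma adjusted p of Mkrn3 was 0.00581 at a difference of 2.19, against 2.20 without it. The limma p of Ndn adjusted over its list was 0.00113 with the score at a difference of 2.52, against 2.55 without it. The order of the arrays after quantile normalization without background correction cannot decide whether that correction made the differences. It keeps the order of probes within an array, so 6 null arrays above all wildtype arrays could hardly fail to recur. Detection, which compares raw intensity with negative controls, found both genes on 6 null arrays and 0 wildtype arrays. In raw intensity 6 null arrays of Mkrn3 and 5 of Ndn lay above all wildtype arrays. These values argue against the correction as the whole source. The size does depend on it, since uncorrected values, in which the background narrows differences of dim probes, gave 0.96 in place of 2.20 for Mkrn3. Its call was lost there. Loss of silencing with the loss of Smchd1 may be the biological explanation, a hypothesis not tested itself, since these arrays measure neither alleles nor DNA methylation.

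On null 6 the Y-linked genes Eif2s3y and Ddx3y stood below the other null arrays. A poor array is argued against by the share of probes detected on it, 36.0%, within the range of the other arrays, and a sample of a wildtype animal by its Smchd1 value of 5.21, within the range of null arrays. A female animal and a loss of the Y chromosome in a male tumour cannot be told apart, because Xist was detected on 0 of the 12 arrays, so that nothing shows that its probes work. Ddx3y was still detected on null 6. No biological explanation that the design names was tested, since the labels give no sex.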

How the results depend on the processing

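All alternatives were chosen before the data were examined except 3, the arrays wildtype 1 and null 1 left out, these and wildtype 2 and null 2 left out, and 2 principal components of the deviations as covariates. Signal over background limits what the arrays show for dim genes, since Mkrn3 and Ndn lie at background in wildtype tumours. Smchd1 stayed lower in all 31 alternatives (between -4.80 and -2.02, the latter with its probes averaged) and past the threshold in all but slide 2 alone, and the Snrpn cluster list kept its direction and call in all 33 it could be tested in, between 0.584 and 1.604. It had too few members under the stricter detection filter. With the stricter filter fewer probes, and on each slide alone fewer arrays, enter the fit. Each slide alone was also normalized and filtered anew, so its list means can rest on other members. For the other changes the cause was not tested.

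The number of probes past the threshold was 1 on slide 1 alone, 0 on slide 2 alone (where 3 arrays per genotype remained), 7 with 2 principal components as covariates and 6 without wildtype 1, wildtype 2, null 1 and null 2. Leaving out 1 array gave 3 to 5 probes, the highest without wildtype 2. The components leave the difference as it is and remove spread between arrays. Besides the 3 genes, the calls added were 1700030C10Rik (array weights, 2 components, without wildtype 2 and without the 4 arrays), Pkp4 (2 components, without null 5), Fzd10 (2 components, without wildtype 2 and without the 4 arrays), Pisd-ps3 (2 components) and Ncam1 (without the 4 arrays). The Fzd10 call came from probe 380551 with 2 components and from probe 6200634 in the other settings. Smchd1 on slide 2 alone differed by -4.04 (adjusted p = 0.0858, range over the alternatives 1.42e-06 to 0.0858), and between -4.64 and -4.23 with 1 array left out. The count of called genes near Smchd1 was 0 on slide 1 alone, on slide 2 alone and with probes of a gene averaged, and 1 with any 1 array left out.

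The number of gene lists past the threshold was 0 with the stricter detection filter, 10 on slide 1 alone, 13 on slide 2 alone, 10 with the sex marker score, 7 with the B cell stage score, 1 without wildtype 1 and null 1, 1 without the 4 arrays, 1 with the estimated correlation and 1 with fry. It was 2 to 8 with 1 array left out, at 5 or more without wildtype 3, 4 or 6 or null 1, 3, 4 or 5. The brackets that follow end with the camera adjusted p at the preset correlation. With the sex marker score Myc target (0.0284), G1/S (0.0140), G2/M (0.00196), mature B cell (0.0168) and interferon response genes (6.93e-05) passed in turned directions. Immediate early and stress genes passed too (0.26, 0.0242). With the B cell stage score G1/S (0.22, 0.00157), G2/M (0.24, 3.73e-05), T cell (-0.33, 0.0271) and Y-linked genes (-0.57, 0.0271) passed. The replicate numbers do not pair the arrays throughout, with correlations of the deviations from -0.25 to 0.66, over 0.1 for 4 pairs. With the replicate block 3 probes and 4 lists passed. The list gained was that of germinal centre and plasma cell markers (-0.28, camera adjusted p = 0.0336).

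On slide 1 alone these lists passed in the direction they had over all arrays: Myc target genes 0.27, G1/S genes 0.70, G2/M genes 0.87, mature B cell markers -0.52, T cell markers -1.13, interferon response genes -0.44 and chromatin silencing factors 0.26. All 7 passed on slide 2 alone in the other direction, given below, at adjusted p from 7.52e-08 to 0.0354. Wildtype 1, on slide 1, and null 1, on slide 2, were the most extreme arrays of their genotype for all 7 lists. Both were low for Myc target, G1/S (7.87 and 8.77), G2/M and chromatin silencing genes. They were high for mature B cell, T cell and interferon response genes. Being of opposite genotype, they push these differences in opposite directions on their slides. An effect of the slides was not tested apart from these tumours. Y-linked genes passed on slide 1 alone (-1.07), and pro-B and pre-B cell markers (-1.17), monocyte markers (0.61), p53 target genes (0.25) and tumour suppressors (0.32) on slide 2 alone. These calls use the preset correlation. Over all arrays camera with the estimated correlation gave an adjusted p of 0.920 for interferon response genes. It gave 0.828 for chromatin silencing factors and 0.771 for tumour suppressors.

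Directions turned as follows. On slide 1 alone the mean differences were Hox genes 0.078, p53 target genes -0.0098, tumour suppressors and survival genes of Myc lymphoma -0.26, pro-B and pre-B cell markers 0.60, monocyte, macrophage and granulocyte markers -0.21, immediate early and stress genes -0.017 and the gene Pcdhgc5 0.34. On slide 2 alone they were clustered protocadherins -0.46, Myc target genes -0.23, G1/S genes -0.50, G2/M genes -0.75, mature B cell markers 0.34, T cell markers 0.73, NK and cytotoxic cell markers 0.035, interferon response genes 0.40, chromatin silencing factors -0.20, Fen1 -0.19, Rpa2 -0.014 and Tap1 0.024. With the sex marker score they were Myc target genes -0.16, G1/S genes -0.25, G2/M genes -0.35, mature B cell markers 0.43, T cell markers 0.43, interferon response genes 0.38, chromatin silencing factors -0.082, Y-linked genes 0.056, Atp10a -0.28, Apoe 0.075 and Ddx3y 0.0025. Without wildtype 1 and null 1 they were clustered protocadherins -0.16, Myc target genes -0.0090, G1/S genes -0.054, G2/M genes -0.024, chromatin silencing factors -0.035 and Atp10a -0.026. Without the 4 arrays they were G1/S genes -0.037, G2/M genes -0.011, erythroid and megakaryocyte markers -0.23, immediate early and stress genes -0.019, chromatin silencing factors -0.016, Atp10a -0.0052, Slc4a1 -0.033, ERAF -0.017 and Car1 -0.55. Immediate early and stress genes were at -0.028 with the B cell stage score, -0.023 with array weights and -0.016 with the stricter filter, where Myc target genes were at -4.4e-04. Atp10a was at -0.032 without background correction and -0.045 with an offset of 50. With probes of a gene averaged Tmem143 was at 0.064 and Ube3a at -0.17.

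With 1 array left out, the mean difference ranged from -0.14 to 0.24 for clustered protocadherins, -0.012 to 0.13 for other imprinted genes, -0.10 to 0.11 for Myc target genes, -0.25 to 0.30 for G1/S genes, -0.28 to 0.35 for G2/M genes, -0.47 to 0.28 for mature B cell markers and -0.70 to 0.15 for T cell markers. It ranged from -0.039 to 0.42 for monocyte, macrophage and granulocyte markers, -0.19 to 0.16 for interferon response genes, -0.079 to 0.16 for immediate early and stress genes, -0.079 to 0.066 for chromatin silencing factors and -0.18 to 0.44 for Atp10a. The direction held for p53 target genes (0.084 to 0.21), pro-B and pre-B cell markers (-0.70 to -0.14), germinal centre and plasma cell markers (-0.46 to -0.022), Y-linked genes (-0.65 to -0.18), Hox genes (-0.20 to -0.026) and tumour suppressors (0.046 to 0.15). It also held for stromal (-0.27 to -0.068), NK (-0.84 to -0.32) and erythroid markers (0.40 to 1.01). The lists that passed with 1 array left out are named in the report.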

Other observations

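The relation between proliferation and T cell markers was noticed in the data, and its test was chosen only after the result was seen. The genes Cdkn2a and Myc were also chosen after their values were seen.

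Some tumours of opposite genotype resembled each other in their list means, which were compared by eye without a clustering. The pairs numbered 1 and 2 share a replicate number, and their deviations from the group means correlated at 0.66 and 0.65. Wildtype 1 and null 1 had high mature B cell markers (log2 means of 11.72 and 11.49), while the other 10 tumours lay at 10.24 or lower. The same pair had high T cell markers (7.86 and 9.08) and low G2/M genes (7.52 and 8.19), while wildtype 6 had T cell markers at 7.59 with G2/M genes at 9.60. Wildtype 2 and null 2 had low pro-B and pre-B cell markers (4.94 and 5.39), as did null 5 (5.37). Monocyte, macrophage and granulocyte markers were high on wildtype 2 and null 2 (7.27 and 7.96), with null 1 close at 7.16. Pro-B and pre-B cell markers were highest on wildtype 4 (7.77). Erythroid markers were highest on null 2 (8.16), null 1 (8.07) and wildtype 5 (7.62), and NK markers on wildtype 1 (7.54) and wildtype 6 (7.07).

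Cdkn2a, a tumour suppressor gene that Myc lymphomas often disrupt, had log2 values of 11.88 and 12.10 on wildtype 3 for 2 of its probes. The highest values of these probes on the other arrays were 8.01 and 7.49, both on null 2. Myc itself was at 8.84 ± 0.75 in wildtype and 8.94 ± 0.26 in null tumours (SD, n = 6 each).

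Across the 12 arrays the mean of the G2/M genes fell where the mean of the T cell markers was high. Pearson's r was -0.83 (permutation p = 0.00291, adjusted 0.00776) and Spearman's rho -0.87 (permutation p = 4.90e-04, adjusted 0.00339), 1 of 8 relations computed with the G2/M mean. Without wildtype 1 and null 1, the 2 arrays farthest from the median of the T cell markers, r was -0.65 (permutation p = 0.0332). Over the 6 arrays of slide 1, which include wildtype 1, r was -0.99. Over the 6 of slide 2, which include null 1, it was -0.89. The values per slide are therefore no check apart from those 2 arrays. A varying share of resting normal lymphocytes in the sorted samples may be the cause, which a sort on tumour markers would reduce, and no measure of tumour purity is given against which to test it. The relation with mature B cell markers (r = -0.80, adjusted permutation p = 0.0144, rho = -0.47, adjusted permutation p = 0.145) rested on wildtype 1 and null 1, since r was 0.04 without them. The relations with interferon response genes (r = -0.80, adjusted permutation p = 0.00128, rho = -0.78, adjusted permutation p = 0.00699) and immediate early and stress genes (r = -0.84, adjusted permutation p = 0.00128, rho = -0.85, adjusted permutation p = 0.00339) remained at r of -0.76 and -0.89 without the 2 arrays farthest from their medians. For NK markers r was -0.68 (adjusted permutation p = 0.0318) and rho -0.83 (adjusted permutation p = 0.00339), with r of -0.98 on slide 1 and -0.07 on slide 2. Without wildtype 1 and wildtype 6 it was -0.57 (permutation p = 0.0904), of similar size and no longer under 0.05. For monocyte markers r was -0.52 (adjusted permutation p = 0.103) and rho -0.81 (adjusted permutation p = 0.00412), and for stromal markers r was -0.52 (adjusted permutation p = 0.0984) and rho -0.72 (adjusted permutation p = 0.0140). Without the 2 arrays farthest from the median r was -0.59 (permutation p = 0.0745) for monocyte and -0.41 (permutation p = 0.239) for stromal markers. For erythroid markers r was -0.27 (adjusted permutation p = 0.419) and rho -0.19 (adjusted permutation p = 0.558).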
